A study of Mus musculus with 4 samples.

How the data were processed

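RNA sequencing libraries of mouse type 1 innate lymphoid cells (ILC1s), selected by surface CD49a per the series' design text, were compared between 2 genotypes. The control cells came from mice with floxed Inpp4b alleles, and the cells labelled knockout came from mice that also carried the Ncr1-iCre transgene. Ncr1 is the gene of the natural killer receptor NKp46. Each genotype was represented by 2 libraries, numbered 1 and 2 for the controls and 3 and 4 for the knockouts in the labels. Liver is named as the tissue of control library 1, while the other libraries carry only the cell type. Total RNA was extracted with a column kit, and low-input SMARTer libraries were sequenced on a NovaSeq, per the labels' protocols.

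The authors deposited 1 table of raw read counts per gene with a column for each library, and the values were whole numbers with unequal totals. Per the submitters' processing notes, bcl2fastq, STAR, Subread, featureCounts and DESeq2 were used with the mm10 mouse assembly. The role of each tool, the gene annotation and the strand setting of the counting were not given in the sources used here. Reads of overlapping or antisense genes could therefore not be told apart, and reads of near-identical copies may have been dropped or split. This bears on the Klra (Ly49) genes, the Ifitm genes, the class II histocompatibility genes, Lyz2, Tubb5 and the T cell receptor segments, whose values are uncertain for that reason. The table held 40757 lines for 40481 Ensembl genes. The 276 repeated lines, whose counts were identical to the first, were dropped. No per-sample column was left unused. Positions were taken from the GENCODE M21 annotation of the same assembly, which held 40254 of the genes.

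Library totals ranged from 42380840 to 54878210 counts. The replicates of each group differed far beyond sampling noise, with a chi-square of 101.6 per degree of freedom over 14444 genes in the controls and 90.81 over 14109 genes in the libraries labelled knockout, so each library was counted as a separate sample. Nothing in the labels says that the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical. The intervals of segment shares and the floors cover counting error only, and understate it since reads without molecular identifiers are not independent molecules.

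Genes were filtered with filterByExpr, scaled with TMM factors and tested with edgeR 4.0.16 (quasi-likelihood test with robust estimation, two-sided) in R 4.3.3, with genotype as the only term. The fit left 2 residual degrees of freedom. Adjusted p-values followed Benjamini-Hochberg over 14863 genes, with a threshold of 0.05. Levels are given as TMM-scaled CPM (counts relative to the scaled library total), fold changes as log2 of the libraries labelled knockout over control, and errors as the standard error (SE) of the fit, which also gave the interval of Inpp4b, or the standard deviation (SD) between 2 libraries. A gene at 0 in every library of a group was compared with a floor of 3 counts per library. The presence of the iCre transgene and the loss of Inpp4b cannot be separated in this design.

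In all, 33 gene lists were written before the data were examined, as were the comparison, its test, the rule for named genes and the alternatives. The lists covered ILC1 and natural killer (NK) cell identity and function, cell survival, phosphoinositide and AKT signalling, FOXO targets, metabolism, proliferation, stress and signalling responses, ribosomal and mitochondrial genes, and markers of other cell types that a liver sort could hold. Inpp4b was left out of each. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry. Each list's median was also set against 10000 random lists of the same size matched on mean expression, a test added after the data were seen.

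Named genes were Inpp4b, Ncr1 and 20 further genes fixed beforehand, up to 12 genes in each direction, and up to 4 members with the smallest p in each list. The genes taken for their size of change had to pass the threshold, to average at least 10 CPM, to lie on the same side in both libraries of each group and to carry an official symbol. Where fewer than 12 passed in a direction, all were taken and filled up to 5 with genes that met all but the adjusted p, by smallest p. Some genes that the rule names are not reported. Genes named outside this rule were chosen after their values were seen. Among them are Cd74, Gzmk, Cd8a, Cd8b1, Mmp8, Mmp9, S100a8, Clec4f, Alb, Cd3g and Trbc1, for which this is not repeated where they are named.

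The alternatives were DESeq2's size factors, upper-quartile factors, no filter on low counts, a stricter filter of 50 counts in 2 libraries, DESeq2 1.42.0, limma-voom, non-robust edgeR, thinning to the smallest library, removal of other-cell, ribosomal and mitochondrial genes, other thresholds, and each library left out in turn. The procedure was tested on simulated counts with the means and library sizes of this comparison and 200 changed genes. The changed genes were drawn only from those above a minimum mean level. The spread was taken from the trend over expression, not from each gene. Recovery of genes with fewer counts or a wider spread than the trend was therefore not tested. Over 14307 genes, edgeR recovered 43.28% of genes changed 2-fold, 88.06% of those changed 4-fold and 100% of those changed 8-fold, with 13 false calls. limma-voom recovered 41.79%, 85.07% and 98.48% of these with 6 false calls, and DESeq2 47.76%, 95.52% and 100% over 14863 genes with 44 false calls. In a second simulation over 14326 genes, camera with the preset correlation called the 1 list that was shifted and 0 of the 32 others, while camera with an estimated correlation missed the shifted list (adjusted p = 0.168).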

Results

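Gene expression was measured by RNA sequencing in mouse type 1 innate lymphoid cells (ILC1s), tissue-resident relatives of natural killer (NK) cells, selected by the integrin CD49a. Libraries from mice with floxed Inpp4b alleles served as controls (n = 2). Libraries labelled knockout came from mice that also carried the Ncr1-iCre transgene (n = 2). Control libraries 1 and 2 held 54878210 and 48491980 counts, and libraries 3 and 4, labelled knockout, held 42380840 and 54125080. The series addresses whether the phosphatase INPP4B, which acts on the phosphoinositide PI(3,4)P2 upstream of AKT, sustains ILC1s.

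Inpp4b transcripts were not lower in the libraries labelled knockout. Inpp4b (ENSMUSG00000037940, mm10 chromosome 8, 81342556 to 82127914) reached 78.7 and 106.5 CPM in the control libraries and 142.5 and 86.0 CPM in the libraries labelled knockout. The group means were 92.6 ± 19.7 and 114.2 ± 40.0 CPM (SD, n = 2 each). The log2 fold change was 0.30 (SE 0.28, edgeR adjusted p = 0.828), with a 95% interval of -0.37 to 0.98. It was -0.13 without knockout library 3. The table sums all exons of the gene, and the exons that the floxed allele removes were not given in the sources used here. The whole-gene count thus neither checks nor contradicts a deletion of part of the gene. Every direction below is that of the libraries labelled knockout, in which the targeted transcript was not lower. Ncr1, the activating receptor gene after which the iCre transgene is named, lies at 4337724 to 4345164 of chromosome 7. Ncr1 was at 1672 and 1772 CPM in controls and 1202 and 1077 CPM in the libraries labelled knockout. Its log2 fold change of -0.60 (SE 0.14, edgeR adjusted p = 0.28) did not pass the threshold.

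**Figure D1:**
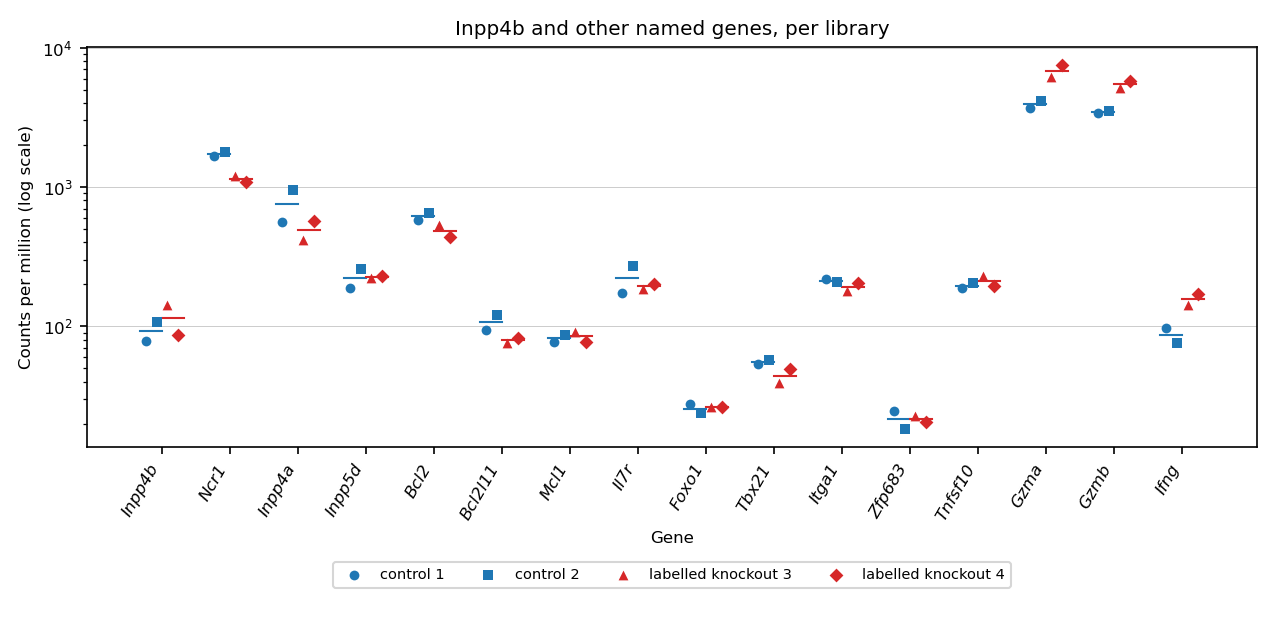
TMM-scaled CPM (log axis) of Inpp4b, Ncr1 and other named genes in each of the 4 libraries, with a bar at each group's mean. Inpp4b lies at 78.7 and 106.5 CPM in controls and 142.5 and 86.0 CPM in the libraries labelled knockout, and no gene shown passed the edgeR threshold.

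Genes of myeloid and antigen-presenting cells were among those that rose in the libraries labelled knockout, and 7 of the 21 genes that rose stand in the lists of other cell types. Lyz2, which encodes the lysozyme of phagocytes, rose from 43.1 and 71.5 CPM to 626.0 and 582.5 CPM (log2 fold change 3.40, SE 0.27, edgeR adjusted p = 0.0467). The class II histocompatibility genes H2-Ab1 (2.61, SE 0.16), H2-Eb1 (2.74, SE 0.21) and H2-Aa (2.78, SE 0.25), which lie together on chromosome 17, rose as well. Their chaperone gene Cd74 rose from 220.1 and 288.0 CPM to 1008 and 1473 CPM (edgeR adjusted p = 0.0489). Trac, the constant segment of the T cell receptor alpha chain, rose from 7.31 and 5.67 CPM to 85.1 and 200.9 CPM (log2 fold change 4.46, SE 0.45, edgeR adjusted p = 0.0489). The Ly49 receptor genes Klra6 (4.14, SE 0.46) and Klra7 (3.56, SE 0.38) also rose, Klra7 from 27.8 and 37.5 CPM to 250.8 and 520.6 CPM (edgeR adjusted p = 0.0489 for both).

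In total 21 genes were higher and 2 lower at an edgeR adjusted p under 0.05, out of 14863 tested. At an unadjusted p under 0.05, 666 were higher and 769 lower. After Trac and Klra6, the largest rises past the threshold among genes of at least 10 CPM were those of Tgfbi (3.81), an extracellular matrix protein gene, and Clec4a3 (3.77), a lectin gene of myeloid cells. Clec4a1 (3.19), a related lectin gene, Serpine2 (3.63), a protease inhibitor gene, Fcgr4 (3.10), an Fc receptor gene of monocytes and macrophages, and Cd300a (3.02), an inhibitory receptor gene of leukocytes, rose too. Csf1r (2.68), the gene of the receptor for macrophage colony-stimulating factor, was named as a list member and was also called. Further calls outside the naming rule, chosen after their values were seen, were Cybb (2.45), Ctss (2.47), Ifitm2 (1.77) and Ifitm3 (2.53). Another was Lilra5 (4.09), at 4237754 to 4243463 of chromosome 7. Stom, also chosen after its values were seen, had 0 counts in both control libraries and 406 and 514 counts in the libraries labelled knockout. That is at least 164-fold higher against a floor of 3 counts per library. Both genes that fell were outside the naming rule and were chosen after their values were seen. Gm12940 fell from 62.1 and 67.6 CPM to 17.4 and 14.4 CPM (log2 fold change -2.03, SE 0.22, edgeR adjusted p = 0.0489). Gm47283, an annotated gene of chromosome Y at 90784738 to 90816464, fell from 1582 and 3626 counts to 0 and 4 counts. This gene alone does not give the sex of the mice, which was not tested.

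These calls lay close to the threshold, with edgeR adjusted p-values from 0.0291 to 0.0489, and DESeq2 called 278 genes higher and 204 lower, all 23 among them. edgeR called 1 higher and 2 lower without control library 1, 1 and 0 without control library 2, 18 and 0 without knockout library 3, and 0 and 0 without knockout library 4, where 1452 genes had an unadjusted p under 0.05.

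**Figure D2:**
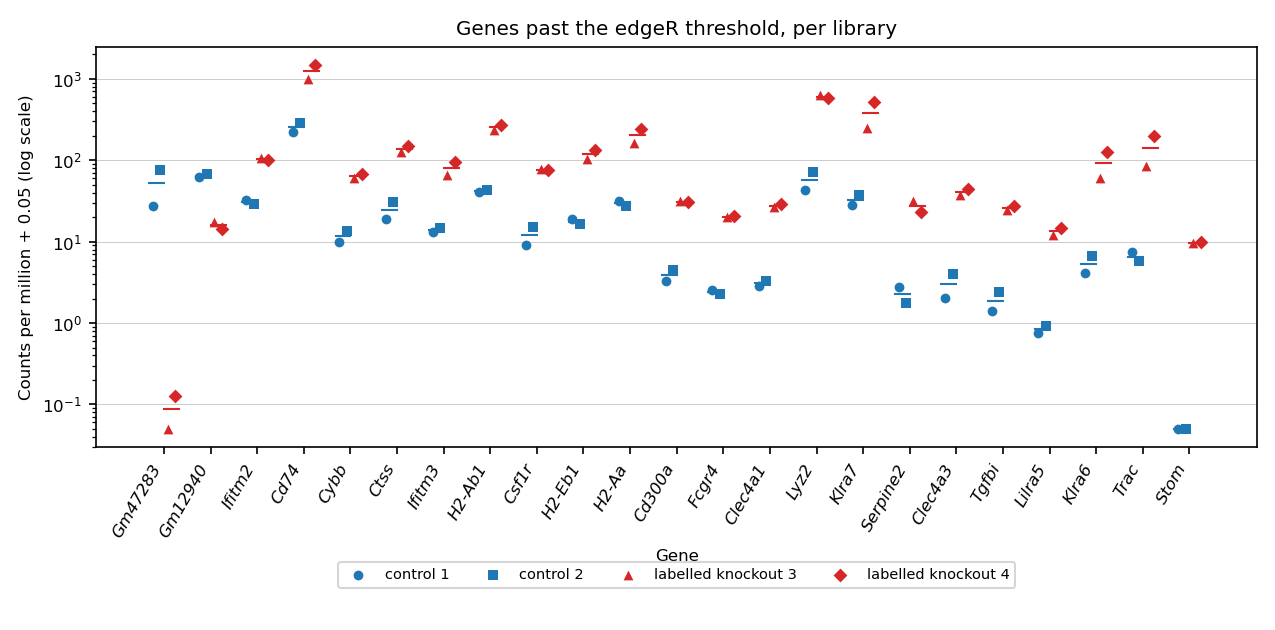
TMM-scaled CPM plus 0.05 (log axis) of the 23 genes past the edgeR threshold in each of the 4 libraries, ordered by log2 fold change, with a bar at each group's mean. Lyz2 is at 626.0 and 582.5 CPM in the libraries labelled knockout against 43.1 and 71.5 CPM in controls, and Stom had no count in either control library.

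Markers of other cell types were higher to unequal degrees in the libraries labelled knockout. Of 17 tested markers of monocytes, dendritic cells and neutrophils, 5 rose over all genes and 10 adjusted over the list alone, with a median log2 fold change of 2.30. Camera placed this list above other genes (adjusted p = 5.7e-16, but adjusted p = 0.37 with an estimated correlation). Its summed level was 997.8 and 1099 CPM in controls and 2975 and 3512 CPM in the libraries labelled knockout. Of its neutrophil genes, S100a8 had a log2 fold change of -0.47 (edgeR adjusted p = 0.989), while Mmp8 (4.60, edgeR adjusted p = 0.329) and Mmp9 (1.01, edgeR adjusted p = 0.289) were called higher by DESeq2. Of 17 Kupffer cell and macrophage markers, 2 rose over all genes (Lyz2 and Csf1r) and 6 adjusted over the list alone. Their median was 0.79 (camera adjusted p = 2.3e-06, but adjusted p = 0.37 with an estimated correlation). Adgre1, which encodes F4/80, was at 2.57 and 2.77 CPM in controls and 18.8 and 16.6 CPM in the libraries labelled knockout (edgeR adjusted p = 0.0684). Clec4f, restricted to Kupffer cells, was at 5.69 and 4.81 against 4.79 and 0.68 CPM (edgeR adjusted p = 0.828). Of 16 T cell markers, 1 rose over all genes (Trac) and 5 adjusted over the list alone. Their median was 0.84 (camera adjusted p = 2.3e-06, but adjusted p = 0.49 with an estimated correlation). Cd3e, a subunit of the T cell receptor complex, was at 26.5 and 15.1 CPM in controls and 152.5 and 371.0 CPM in the libraries labelled knockout (log2 fold change 3.65, edgeR adjusted p = 0.095). Tcrg-C2, a gamma chain constant segment, was at 6.40 and 5.04 against 40.5 and 125.3 CPM (3.86, edgeR adjusted p = 0.118). Cd8a was at 15.2 and 19.7 against 59.8 and 141.3 CPM (2.53, edgeR adjusted p = 0.172) and was called by DESeq2, and Cd8b1 was at 0.03 and 1.61 against 0.12 and 0.66 CPM.

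Markers of hepatocytes moved little in the median, but their sum differed between the controls. It was 896.2 and 423 CPM in controls and 984.7 and 826.4 CPM in the libraries labelled knockout. The direction of the list was down without control library 2. The 29 hepatocyte markers had a median of 0.24 (camera adjusted p = 0.00326, but adjusted p = 0.55 with an estimated correlation), and Alb, the albumin gene, had a log2 fold change of 0.13. edgeR called 0 of them over all genes or adjusted over the list alone, with 3 higher and 0 lower at an unadjusted p under 0.05, and DESeq2 called Hp. The 10 endothelial and stellate cell markers had a median of 0.78 but a mean of -0.09 (camera direction up, adjusted p = 0.266). The 12 erythroid and platelet markers had a median of 0.16 but a mean of -0.20 (camera direction down, adjusted p = 0.906). The 10 B cell and plasma cell markers had a median of 0.23 (camera adjusted p = 0.435), and the 8 ILC2 and ILC3 markers a median of 0.65 (camera adjusted p = 0.064). edgeR called 0 of these 40 markers over all genes, with 7 higher and 3 lower at an unadjusted p under 0.05, and DESeq2 called 4 higher and 1 lower. Adjusted over the list alone, the endothelial genes Dnase1l3 and Fcgr2b were higher and Gpr182 lower. In the same way the platelet genes Itga2b and Gp9 were lower.

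**Figure D3:**
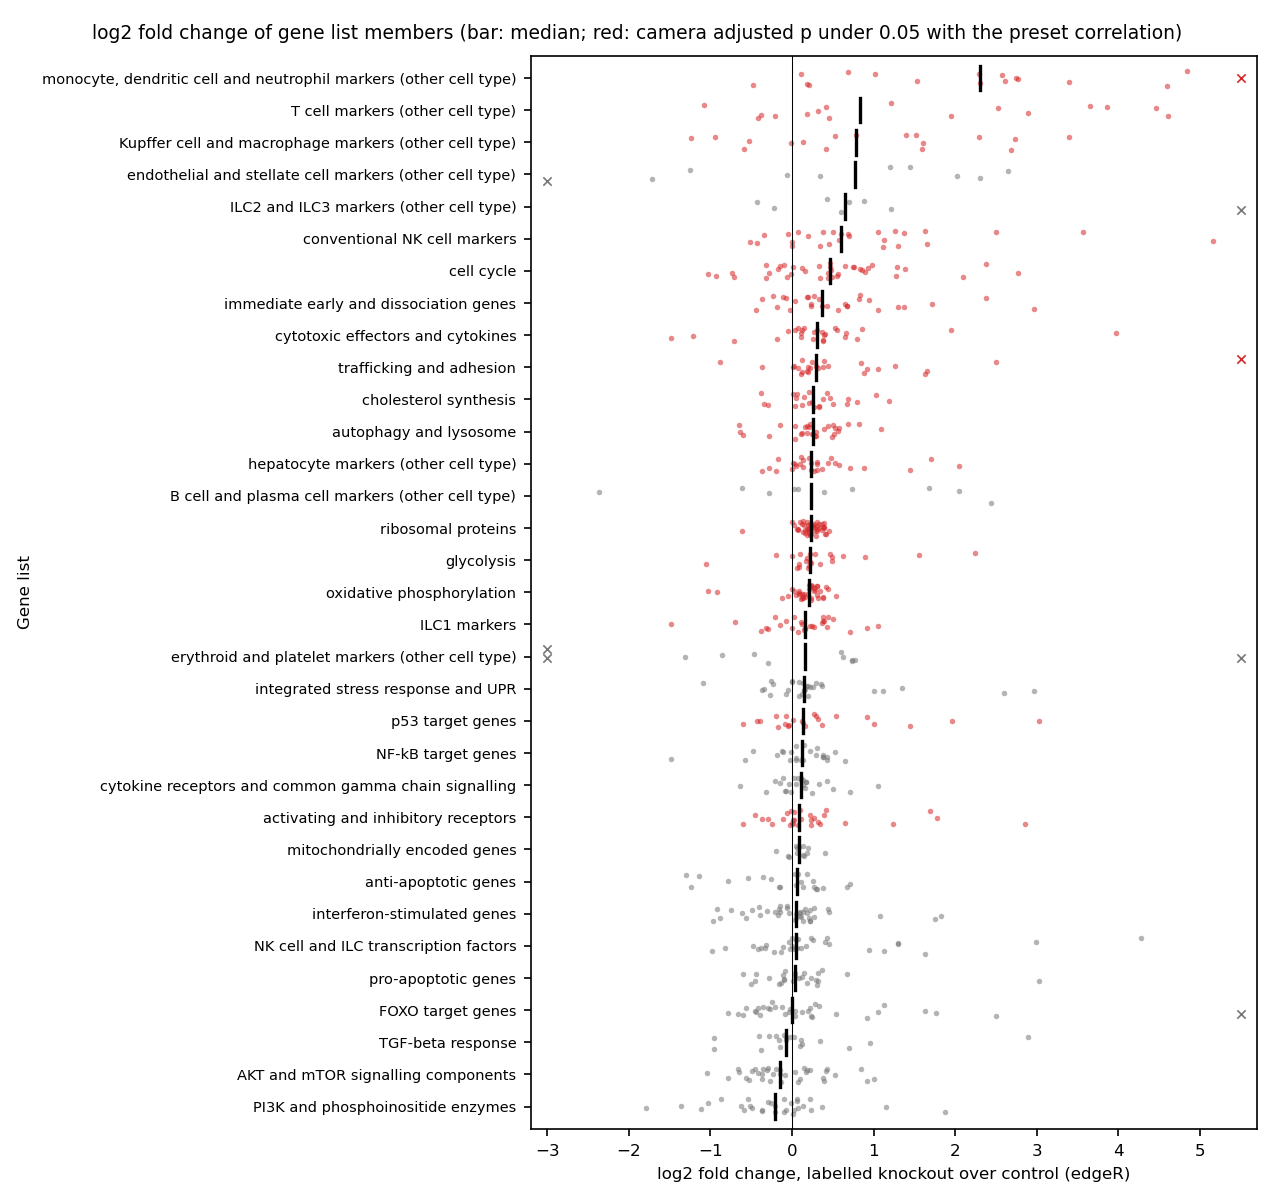
edgeR log2 fold changes (libraries labelled knockout over control) of the tested members of each of the 33 gene lists, 1 point per gene, with a vertical bar at the median. Crosses are members beyond the axis range and red marks lists with a camera adjusted p under 0.05 at the preset correlation. The monocyte, dendritic cell and neutrophil markers have the highest median, 2.30, and the PI3K and phosphoinositide enzymes the lowest, -0.20.

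Genes of cytotoxic function were higher as a list in the libraries labelled knockout, in which markers of myeloid and T cells were higher too. Camera placed the 27 cytotoxic effectors and cytokines above other genes (median 0.31, adjusted p = 3.3e-05, but adjusted p = 0.37 with an estimated correlation). edgeR called 0 of them over all genes, with 8 higher and 2 lower at an unadjusted p under 0.05, while 5 were called higher adjusted over the list alone and 5 by DESeq2. Gzma, a granzyme gene, was at 3694 and 4126 CPM in controls and 6110 and 7481 CPM in the libraries labelled knockout (log2 fold change 0.80, SE 0.16, edgeR adjusted p = 0.239). Gzmb was at 3387 and 3518 against 5120 and 5797 CPM (0.66, SE 0.14, edgeR adjusted p = 0.251). Ifng, the interferon-gamma gene, was at 97.8 and 75.8 against 142.7 and 171.4 CPM (0.86, SE 0.19, edgeR adjusted p = 0.277). The other members called over the list alone were Srgn (0.55) and the granzyme gene Gzmk, which was at 1.31 and 0.55 CPM in controls, 3.47 CPM in knockout library 3 and 25.9 CPM in knockout library 4.

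ILC1 identity genes differed little. The 29 ILC1 markers had a median of 0.16 (camera adjusted p = 0.00744, but adjusted p = 0.37 with an estimated correlation). edgeR called 0 of them over all genes or adjusted over the list alone, with 7 higher and 0 lower at an unadjusted p under 0.05, and DESeq2 called 0. Itga1, the gene of CD49a, was at 217.6 and 207.9 CPM in controls and 178.9 and 206.0 CPM in the libraries labelled knockout. Tbx21, which encodes T-bet, was at 53.4 and 57.0 against 39.4 and 49.0 CPM, and Zfp683, which encodes Hobit, at 24.8 and 18.4 against 22.8 and 20.5 CPM. Tnfsf10, the TRAIL gene, was at 188.0 and 203.2 against 229.4 and 193.7 CPM, and Kit at 50.5 and 105.5 against 65.6 and 31.0 CPM.

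Of 27 conventional NK cell markers, Klra7 rose over all genes and also adjusted over the list alone. The median was 0.60 (camera adjusted p = 2.1e-05, but adjusted p = 0.37 with an estimated correlation). Klra1, a further Ly49 gene, was at 3.74 and 5.97 CPM in controls, 18.99 CPM in knockout library 3 and 327.5 CPM in knockout library 4 (edgeR adjusted p = 0.303). Eomes and Itga2, which mark conventional NK cells, had log2 fold changes of 1.13 (edgeR adjusted p = 0.703) and -0.34 (edgeR adjusted p = 0.866).

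The 30 activating and inhibitory receptors had a median of 0.09 (camera adjusted p = 0.0214, but adjusted p = 0.37 with an estimated correlation). This median lay at percentile 45.08 of the random lists matched on expression. edgeR called 0 of them over all genes, with 6 higher and 2 lower at an unadjusted p under 0.05. Adjusted over the list alone, the inhibitory receptor genes Havcr2 (2.10 and 1.52 against 15.4 and 10.9 CPM) and Pdcd1 (11.6 and 14.2 against 31.3 and 52.1 CPM) were higher and Ncr1 was lower, beside the higher markers of myeloid and T cells. DESeq2 called the same 3. The 33 NK cell and ILC transcription factors had a median of 0.05 (camera adjusted p = 0.201). edgeR called 0 over all genes, with 5 higher and 1 lower unadjusted, and DESeq2 called 2 higher and 1 lower. Adjusted over the list alone, Myc was lower, at 154.2 and 193.1 CPM in controls and 86.2 and 89.8 CPM in the libraries labelled knockout (log2 fold change -0.98, SE 0.17, edgeR adjusted p = 0.182). Klf2, a quiescence and trafficking factor gene, was at 1.03 and 0.89 against 3.16 and 2.80 CPM (edgeR adjusted p = 0.494). The 27 trafficking and adhesion genes had a median of 0.29 (camera adjusted p = 2.1e-06, but adjusted p = 0.37 with an estimated correlation). edgeR called 0 of them over all genes or adjusted over the list alone, with 7 higher and 0 lower unadjusted, and DESeq2 called Ccr7 among those higher.

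Genes of cell survival showed no shift that passed an edgeR or camera test at the level of apoptosis regulators. Bcl2, the anti-apoptotic gene, was at 574.8 and 653.4 CPM in controls and 529.1 and 434.3 CPM in the libraries labelled knockout (log2 fold change -0.35, SE 0.16, edgeR adjusted p = 0.55). Bcl2l11, which encodes the pro-apoptotic BIM, was at 93.5 and 121.0 against 76.3 and 81.9 CPM (-0.44, SE 0.18, edgeR adjusted p = 0.523). Mcl1 (0.04, SE 0.17) and Il7r (-0.20, SE 0.23) differed by less than the spread between replicates. The 22 anti-apoptotic genes had a median of 0.07 but a mean of -0.11 and a camera direction of down (adjusted p = 0.641). The 26 pro-apoptotic genes had a median of 0.03 (camera adjusted p = 0.218). edgeR called 0 of the anti-apoptotic genes over all genes or over the list alone, with 0 higher and 4 lower unadjusted, and DESeq2 called Pim1 and Birc6 lower. edgeR likewise called 0 of the pro-apoptotic genes, with 2 higher and 0 lower unadjusted, and DESeq2 called Pmaip1, the Noxa gene, higher. Pim1, a survival kinase gene, was at 318.3 and 706.0 against 229.6 and 203.2 CPM, and Birc6, an inhibitor of apoptosis gene, at 226.1 and 313.6 against 149.4 and 163.5 CPM. The 23 p53 target genes had a median of 0.13 (camera adjusted p = 0.0366, but adjusted p = 0.37 with an estimated correlation). edgeR called 0 of them over all genes or over the list alone, with 4 higher and 0 lower unadjusted, and DESeq2 called 3 higher, among them Cdkn1a (1.97), a cell cycle inhibitor gene.

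The 3 lists around the pathway in which INPP4B acts held no gene that edgeR called. The 31 PI3K and phosphoinositide enzymes had a median of -0.20 (camera direction down, adjusted p = 0.0664). The 36 AKT and mTOR signalling components had a median of -0.15 (camera direction down, adjusted p = 0.512). Against the random lists matched on expression, the PI3K median lay at percentile 0.45, the AKT median at 4.4 and that of FOXO targets at 39.81. The random lists were added after the data were seen and ignore correlation between genes. The 34 FOXO target genes had a median of 0.00 and a mean of 0.34 (camera adjusted p = 0.435), but passed the mixed test of fry, which ignores direction (adjusted p = 0.00035). edgeR called 0 members of these lists over all genes or over the list alone. At an unadjusted p under 0.05 edgeR had 1 higher and 2 lower among the PI3K enzymes, 2 and 2 among the AKT components, and 5 and 2 among the FOXO targets. DESeq2 called Inpp5e lower, and Ddit4 and Ccr7 among those higher. Inpp5e, another inositol phosphatase gene, was at 28.6 and 30.8 CPM in controls and 13.2 and 14.3 CPM in the libraries labelled knockout (log2 fold change -1.11, SE 0.25, edgeR adjusted p = 0.277). Inpp4a, the paralog of Inpp4b, was at 560.7 and 950.2 against 413.6 and 565.8 CPM (-0.63, SE 0.28, edgeR adjusted p = 0.548). Inpp5d (0.01, SE 0.18) and Foxo1 (0.03, SE 0.24) differed by less than the spread between replicates.

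Ribosomal, metabolic and cell cycle genes were slightly higher as lists in the libraries labelled knockout, in which markers of myeloid and T cells were higher too (medians 2.30 and 0.84). Of the 46 ribosomal protein genes, 44 had a log2 fold change above 0, with a median of 0.23 (camera adjusted p = 1.5e-11, but adjusted p = 0.49 with an estimated correlation). The 38 oxidative phosphorylation genes had a median of 0.21 (camera adjusted p = 7.3e-06, but adjusted p = 0.37 with an estimated correlation), and the 23 glycolysis genes one of 0.22 (camera adjusted p = 0.000453, but adjusted p = 0.50 with an estimated correlation). The 24 cholesterol synthesis genes had a median of 0.26 (camera adjusted p = 0.0026, but adjusted p = 0.37 with an estimated correlation), and the 30 autophagy and lysosome genes one of 0.26 (camera adjusted p = 0.000173, but adjusted p = 0.39 with an estimated correlation). The 39 cell cycle genes had a median of 0.47 (camera adjusted p = 0.0104, but adjusted p = 0.49 with an estimated correlation). Mcm2, a replication licensing gene, was at 41.3 and 41.0 CPM in controls and 73.1 and 66.9 CPM in the libraries labelled knockout (edgeR adjusted p = 0.286). Mki67, a marker of cycling cells, was at 0.74 and 1.97 against 2.54 and 4.56 CPM (edgeR adjusted p = 0.623). edgeR called 0 members of these 6 lists over all genes or over the list alone, with 27 higher and 0 lower at an unadjusted p under 0.05. DESeq2 called Slc16a3, Idi1, Mcm2 and Kif20a higher.

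Of the 29 immediate early and dissociation genes, which respond to tissue digestion and sorting, Fos (1.29) and Hspa1a (2.37) were higher adjusted over the list alone, beside the higher markers of myeloid and T cells (medians 2.30 and 0.84). edgeR called 0 over all genes, with 5 higher and 0 lower unadjusted, and DESeq2 called the same 2. The median was 0.37 (camera adjusted p = 4.5e-05, but adjusted p = 0.37 with an estimated correlation). Camera called none of the 6 remaining lists. The 30 genes of the integrated stress and unfolded protein responses had a median of 0.15 (adjusted p = 0.0772), the 24 NF-kB targets 0.12 (adjusted p = 0.0618) and the 40 interferon-stimulated genes 0.05 (adjusted p = 0.623). The 25 genes of cytokine receptors and common gamma chain signalling had a median of 0.11 (adjusted p = 0.201) and the 13 mitochondrially encoded genes 0.09 (adjusted p = 0.379). The 20 TGF-beta response genes had a median of -0.07 but a mean of 0.07 (camera direction down, adjusted p = 0.584). edgeR called 0 members of these 6 lists over all genes, with 7 higher and 5 lower unadjusted. Ifi27l2a (1.76), an interferon-stimulated gene, was called adjusted over the list alone and by DESeq2.

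Among genes that were lower but did not pass the threshold, Srsf2, a splicing factor gene, was at 712.2 and 889.8 CPM in controls and 279.8 and 323.7 CPM in the libraries labelled knockout (log2 fold change -1.41, SE 0.17, edgeR adjusted p = 0.0654). Slc20a1, a phosphate transporter gene (-1.23, SE 0.16, edgeR adjusted p = 0.086), and Arglu1, a splicing modulator gene (-0.93, SE 0.14, edgeR adjusted p = 0.138), followed. Tubb5, a beta-tubulin gene, was at 869.4 and 1837 against 255.5 and 313.4 CPM (-2.25, SE 0.35, edgeR adjusted p = 0.156). Ip6k1, an inositol hexakisphosphate kinase gene, had a log2 fold change of -1.48 (SE 0.24, edgeR adjusted p = 0.166).

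With the preset correlation camera called 17 of the 33 lists, all higher, whereas 0 were called with an estimated correlation and 0 by fry. Camera with an estimated correlation missed a shifted list in simulated data. Those simulated data cannot show whether the preset correlation of 0.01 holds in these libraries, so the 17 calls rest on that setting. The mixed test of fry, which asks whether members move in either direction, called 9 lists. These were FOXO targets (fry adjusted p = 0.00035), activating and inhibitory receptors (0.00208), p53 targets (0.00927), interferon-stimulated genes (0.015), Kupffer cell and macrophage markers (0.021), monocyte, dendritic cell and neutrophil markers (0.021), ILC1 markers (0.0215), conventional NK cell markers (0.0341) and NK cell and ILC transcription factors (0.0341). limma-voom called 1 conventional NK cell marker, 2 Kupffer cell and macrophage markers and 5 monocyte, dendritic cell and neutrophil markers over all genes, and 0 members of the other 30 lists.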

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

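The block by the numbers in the table's column names and the random lists matched on expression were chosen only after the results were seen, and the other alternatives were fixed before. The labels pair no libraries, numbering them 1 and 2 for the controls and 3 and 4 for the libraries labelled knockout. The column names repeat 1 and 2 in each group, which was fitted as a block, and same-numbered libraries deviated together with a correlation of 0.143 over 11968 genes. The totals of 42380840 to 54878210 counts limit the genes of few counts most, and leaving out a library left 1 library in its group, which the fit assumed to vary like the other group.

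The main counts were 21 genes higher and 2 lower. DESeq2's size factors, upper-quartile factors, limma-voom and non-robust edgeR gave counts within 1.5 times these, with all 23 calls kept except in limma-voom, which kept 16 and gave the 23 adjusted p-values of up to 0.388. Without a filter edgeR called 299 higher and 264 lower, with the stricter filter 40 and 9, and DESeq2 called 278 and 204, each with all 23 calls kept; the cause was not tested. A threshold of 0.1 gave 33 higher and 5 lower, and one of 0.01 gave 0 and 0. Thinning to the smallest library gave 3 and 0, where the 23 calls had edgeR adjusted p-values of 0.0291 to 0.063. Without other-cell, ribosomal and mitochondrial genes 0 and 0 passed edgeR, with 1403 genes at an unadjusted p under 0.05. In that setting 7 of the 23 calls were removed by construction and the other 16 had an edgeR adjusted p of 0.0663. The block gave 0 and 0 in edgeR, with 1709 genes at an unadjusted p under 0.05, and the 23 calls at adjusted p-values of 0.0669 to 0.154. The sign of each of the 23 calls was kept in every setting in which it was tested.

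Leaving out each library in turn gave 0 to 18 genes higher and 0 to 2 lower in edgeR. The counts were 1 and 2 without control library 1, 1 and 0 without control library 2, 18 and 0 without knockout library 3 (9 of the 23 calls kept), and 0 and 0 without knockout library 4. The adjusted p-values of the 23 calls then ranged from 0.0324 to 0.148, 0.0184 to 0.195, 0.00884 to 0.161 and 0.0775 to 0.221 in edgeR. Fewer samples were tested in each, and no other cause was tested.

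The log2 fold change of Inpp4b ranged from -0.13 without knockout library 3 to 0.60 without knockout library 4. Other genes whose sign reversed were Mcl1 (-0.11 to 0.13), Il7r (-0.49 to 0.16), Zfp683 (-0.20 to 0.24), Tnfsf10 (-0.034 to 0.20), Foxo1 (-0.066 to 0.14), Inpp5d (-0.20 to 0.26), mt-Nd2 (-0.0038 to 0.32), mt-Nd1 (-0.015 to 0.24), mt-Co1 (-0.11 to 0.43) and Ighm (-0.54 to 0.023). Zfp683 was at -0.021 without a filter, -0.032 with the stricter filter and -0.0026 with limma-voom, and Inpp5d at -0.0029 and -0.011 under these filters; the cause was not tested. Over 1865 comparisons of named genes with an alternative, 1670 kept direction and side of the threshold, 70 no longer passed, 106 newly passed and 19 reversed.

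Camera called 17 of the 33 lists, against 0 with an estimated correlation and 0 by fry (9 by its mixed test), and 13 to 21 under the other alternatives. The direction of 8 lists reversed when a library was left out. Their camera adjusted p-values ranged from 0.0299 to 0.752 for anti-apoptotic genes (up without control library 2), 0.292 to 0.839 for FOXO targets (down without knockout library 4) and 0.0633 to 0.383 for interferon-stimulated genes (down without control library 1 or knockout library 4). They ranged from 0.383 to 0.869 for the TGF-beta response (up without knockout library 3, and up without a filter at 0.697), 0.234 to 0.931 for mitochondrially encoded genes (down without knockout library 4) and 1.8e-09 to 0.836 for hepatocyte markers (down without control library 2). They ranged from 0.142 to 0.869 for B cell markers (down without control library 2) and 0.00769 to 0.776 for erythroid markers (up without control library 1 or knockout library 3); the cause was not tested. Over 363 comparisons of lists, 288 were the same, 48 no longer passed, 16 newly passed and 11 reversed.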

Other observations

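The tests of Kupffer cell, hepatocyte and conventional NK cell genes, of T cell clones and of Inpp4b were chosen only after the results were seen. Those of the independent myeloid list and of Trdv segments were written before their own values were seen. By then the higher myeloid and T cell receptor transcripts were already known.

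The libraries labelled knockout differed from each other in the T cell receptor variable segments they held. In knockout library 3 Trav7-4 held 1027 of 1800 Trav counts (57.1%, exact 95% interval 54.7 to 59.4) and Trbv1 1950 of 3644 Trbv counts (53.5%, 51.9 to 55.1). In knockout library 4 Trav14-1 held 5281 of 6623 Trav counts (79.7%, exact 95% interval 78.7 to 80.7) and Trbv14 3625 of 5795 Trbv counts (62.6%, 61.3 to 63.8). Trav7-4 and Trav14-1 each had 0 counts in the 3 other libraries, and the top Trav segment of the controls, Trav15-1-dv6-1, held 18.7% and 23.8%. Segments have near-identical copies, so that the segment named is uncertain. Trdv segments summed to 167.9 and 199.2 CPM (unscaled) in the controls and 169.3 and 152.6 CPM in the libraries labelled knockout, mostly from Trdv4. Trav segments with at least 10 counts numbered 6 and 7 in the controls and 18 and 14 in the libraries labelled knockout.

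The platelet gene Itga2b was at 4.45 and 1.52 CPM in controls and 0.07 and 0.02 CPM in the libraries labelled knockout. The medians of the endothelial and erythroid lists, 0.78 and 0.16, did not move when genes without counts in a group were set to their bound.

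Myeloid transcripts were higher in both libraries labelled knockout, with a median log2 fold change of 2.91 over 12 phagocyte genes chosen for being high there, and the rise was of similar size in both (median ratio of library 4 to 3 of 1.08). The tables argue against resident Kupffer cells as the whole source. The 10 genes listed for them summed to 22.4 and 16.8 CPM (unscaled) in controls and 16.9 and 19.9 CPM in the libraries labelled knockout. That was at most 0.889 times the higher control, while the 12 phagocyte genes summed to 112.4 and 159.7 against 1116 and 1076 CPM. Members of the sum moved unlike each other. Slc40a1 had 593 and 256 counts in controls against 165 and 601, and Clec4f 330 and 227 against 206 and 35. The tables also argue against hepatocyte RNA as the whole source, since its 29 markers had a median of 0.24 (SE 0.07 over genes). The controls differed in the sum of these markers (896.2 and 423 CPM, against 984.7 and 826.4 CPM). Monocytes or dendritic cells among the sorted cells remain a candidate source. Of 29 tested genes of an independent list of their markers, 20 were higher at an edgeR unadjusted p under 0.05 and 0 passed edgeR. Their median was 1.59, above all 10000 matched random lists. The random lists ignore correlation between genes, and other myeloid genes were known to be higher when the list was written, so that rank adds little. The 2 most abundant genes of the list changed little, Pglyrp1 by 0.15 (149.9 and 197.4 to 174.5 and 210.9 CPM) and Fgr by 0.49 (108.1 and 155.0 to 178.2 and 192.4 CPM). Of the 29, 5 averaged at least 10 CPM in controls and 1 stands in another list. The labels name selection by CD49a, whether that would remove such cells was not tested, and an effect of the genotype on the cells or on the tissue stays open as untested.

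T cell receptor transcripts and the Ly49 genes Klra6 and Klra7 were also higher. The median was 3.65 over 5 T cell genes chosen for being high in the libraries labelled knockout (0.84 over the 16 tested T cell markers). The mean of Klra6 and Klra7, chosen in the same way, was 3.85. Both sets were higher in library 4 than in library 3 (ratios of 2.4 and 2.1). Other Ly49 genes were uneven, and none passed the edgeR threshold. Klra9 (0.08), Klra3 (0.38) and Klra8 (0.50) changed less, Klra4 was at 1.12 and Klra1 at 5.16. Klra9 was at 182.7 and 131.5 CPM in controls and 170.1 and 162.1 CPM in libraries 3 and 4. The tables argue against conventional NK cells as the whole source of the Ly49 part, since 7 other genes of theirs under 10 CPM in controls had a median of 1.12 (SE 0.31). Alpha-beta T cells with a few large clones, different in each library, are a candidate source of most of the T cell receptor part, since the lower of the top Trav shares was 57.1%, although Trbc1 (442.9 and 615.5 against 389.5 and 425.2 CPM) and Cd3g (1469 and 1255 against 1623 and 1930 CPM) were already high in controls. Cells of many clones beside them cannot be told apart from these, since summed Trav segments were at least 14 times the higher control. Those outside each library's top segment, 135 and 112 against 773 and 1342 counts, were 7.41 and 10.1 times the higher control. In libraries 3 and 4 they include 228 and 334 counts of Trav15-1-dv6-1, by its name a segment shared with the delta chain. In the controls that segment, with 31 and 35 counts, was the top one and was left out. Its counts do not separate alpha from delta chains. Gamma-delta T cells cannot be told apart from the rest, since Trdv segments at 0.766 times the higher control had a level in controls far above Trgv2 (3.64 and 3.59 to 21.0 and 64.4 CPM), so that the bound set beforehand would not have seen them, no gate on T cells is stated in the sources used here, and an effect of the genotype on these genes stays open as untested.

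Inpp4b transcripts were not lower over the whole gene (log2 fold change 0.30, 95% interval -0.37 to 0.98, or 0.773 to 1.97 times the control). A large drop in the whole-gene count is outside this interval, but a deletion of some exons that leaves the other exons transcribed cannot be told apart from an undeleted gene, since counts per exon were not used here. The identity of the libraries, the share of cells in which the allele was deleted and the genotype itself stay open as untested.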
